A study of Mus musculus with 12 samples.

How the data were processed

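RNA was sequenced in 12 samples of 3 mouse small cell lung cancer lines: 16T and KP1 with a control shRNA or an shRNA against Nfib, and KP22 with an empty vector or Nfib cDNA, 2 samples in each of 6 groups. Per the labels' protocols, RNA was extracted with a Qiagen kit and libraries were made with an Illumina TruSeq kit; replicates are called duplicates and are not said to be separate cultures, so every p measures only the spread between these samples. Per the submitters' processing notes, TopHat, bedtools, DESeq and DESeq2 were used with the mouse build mm10; their versions and settings are not given in the sources used here.

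The authors' deposited table held results of comparisons, not values per sample. Its name per the labels mentions cqn normalization and deseq. For each of 28112 features the authors gave 1 mean normalized count (a signal over all libraries of their fit, the same under every heading). Per the file headers, 4 comparisons follow, with log2 fold changes and their SEs on the log2 scale, a Wald score, a p-value and an adjusted p-value, and the same for a test against an absolute log2 fold change of 0.5. The score of the deposited tables equalled the log2 fold change divided by its SE. The knockdown comparison equalled the mean of the 16T and KP1 effects, and its SE was that of independent effects (ratios between 0.992 and 1.01). The largest SE was 0.521, and the median SE fell to 0.189 in 16T for features with a mean under 1, so the deposited log2 fold changes look shrunken towards 0. Adjusted p-values were left empty by the authors below a mean of 15.7 in 16T and KP1, 6.57 in the knockdown mean and 0.926 in KP22. The direction of each comparison is not in the headers; it was taken from Nfib, which was below 0 in the shRNA comparisons and above 0 with cDNA.

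Another deposited list gave 211975 exon intervals of RefSeq genes on mm10, none overlapping the one before. Intervals merged from more than 1 exon carry joined names, and 4886 features of the table have such names, 2989 repeating 1 gene and 1897 joining different genes. The 23226 features with 1 gene name held 93.7% of the summed mean counts and were used here; 4926 of them have further exons under a joined name. Where a joined feature and its own gene both had a mean of at least 100 (1468 pairs), Pearson's r of their log2 fold changes across genes was 0.861 in 16T, 0.845 in KP1 and 0.888 in KP22. Positions were compared with GENCODE M21 of the same build: 21914 names matched and 99.4% of these overlapped in position.

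The total count of each library is unknown here, so no depth or counting interval is given. The median mean count of features with 1 name and a mean above 0 was 506. The precision is that of the authors' SEs, whose median in 16T was 0.070 for genes with a mean of at least 1000, 0.176 for 100 to 1000 and 0.445 for 10 to 100.

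Comparisons, gene lists and thresholds were chosen before the data were examined, as were, of the alternatives run, other filters on the mean and a change of at least 1. The other alternatives that were run, and the way the 3 contrasts below were computed, were chosen afterwards. The design had foreseen counts or normalized values per sample, with 1 fit over all 12 libraries; as the table holds results only, the authors' deposited adjusted p-values below 0.05 were used for 16T, KP1, KP22 and the knockdown mean. From the deposited effects and SEs, 3 further contrasts were computed for 15008 genes with a mean of at least 10: the mean of the 3 effects turned towards higher Nfib, the difference between 16T and KP1, and the difference between the knockdown lines and KP22. The comparisons share no samples, so their errors were added as independent, with a normal reference and Benjamini-Hochberg adjustment. On simulated tables of 15008 genes with 200 changed, averaged over 20 tables, the mean of the 3 effects recovered 76.2% of changes of 0.5 and 93.2% of changes of 1 (5.46% and 4.41% of calls false). The difference between 16T and KP1 recovered 47.1% and 72.5% (4.15% and 4.87% false), and that between the knockdown lines and KP22 53.2% and 75.4% (5.15% and 4.96% false). The simulated errors were drawn from a normal distribution at the deposited SEs. The shares of false calls therefore check neither those SEs nor the normal reference. Fewer genes were changed in the simulated tables than were called in the data.

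The 24 gene lists cover the other NFI genes, neuroendocrine identity, a Notch and YAP program, axon guidance, neuronal adhesion, neurotransmitter receptors and channels, and synaptic vesicles. They also cover extracellular matrix, epithelial adhesion, mesenchymal transition, S phase, G2/M, interferon-stimulated genes, stress responses, hypoxia and glycolysis, cholesterol and fatty acid synthesis, and immediate early genes. The rest are chromatin regulators, ribosomal proteins, oxidative phosphorylation, and markers of leukocytes, fibroblasts, endothelium and airway. Nfib is in none of them. Each was tested with the preranked camera test of limma 3.58.1 in R 4.3.3 on the Wald statistics with an inter-gene correlation of 0.01, adjusted over the 24 lists of a comparison. A correlation can be estimated only from values per sample, so 0.05 was used as the other setting. On 100 simulated tables for 16T the camera step recovered 95.0% of shifted lists and called 0.435% of others. In these tables the 16T statistics were permuted over genes and 1 list was shifted by 1 SD. Permuting removes correlation between genes, so the result does not check whether 0.01 is large enough. Overlaps were tested with Fisher's exact test, 2-sided. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

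Genes were named by rule: Nfib; in 16T, KP1 and KP22 the 8 rises and 8 falls with the largest log2 fold change among called genes with a mean of at least 100. For each list it took up to 4 called members with the largest change (up to 2 with the smallest p where none was called). It took up to 15 genes called in all 3 lines with the level of Nfib and up to 10 against it, and 6 genes per difference test. The rule had also asked that the samples of both groups not overlap, which could not be judged. Models without a protein name and genes with near-identical copies were passed over. A few genes that the rule took are not reported here. Of 262 named genes, 56 have further exons under joined names.

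Alternatives were other filters, thresholds and statistics, a t distribution with 6 degrees of freedom, recentring on the median gene, joined features, and leaving out a chromosome 2 region. Alternatives that need values per sample were not run: other normalizations, pseudocounts, a replicate block, leaving out libraries, fits of 1 line alone and permuted groups. The labels name a file of counts beside the table; counts per sample were not used here, and chromatin accessibility was not analysed here.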

Results

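RNA was sequenced from 3 mouse small cell lung cancer lines, 16T, KP1 and KP22, which derive from tumors without Trp53 and Rb1 and grow as floating spheres. The lines 16T and KP1, labelled Nfib high, carried either a control shRNA (shLuc in the titles) or an shRNA against Nfib. The titles give the Nfib shRNA the same name, sh2, in both lines. KP22, labelled Nfib low, carried either an empty vector or a vector with Nfib cDNA. Each of the 6 groups held 2 samples, which makes 12. Nfib encodes a transcription factor of the nuclear factor I (NFI) family, and the title of the series names metastasis and chromatin accessibility. Each comparison asks which transcripts changed where Nfib was lowered or raised. The values were log2 fold changes and SEs from a fit by the authors, with no values per sample, and counts per sample were not used here, so the total counts per sample and the number of samples showing each direction are unknown. A transcript is said to have risen or fallen where its adjusted p was below 0.05, and ± gives the SE.

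Nfib itself was measured on 11 exon intervals of chromosome 4 (82290173 to 82505779, mm10) at a mean normalized count of 30668. The authors' deposited table gave a log2 fold change of -1.08 ± 0.035 in 16T, which is 47.2% of the control level, and of -1.32 ± 0.035 in KP1, which is 40.0%. In KP22 with Nfib cDNA the value in the authors' deposited table was 1.80 ± 0.036, a 3.49-fold increase. The table's headings give no direction, which was read from Nfib, so Nfib is not a separate check of the labels, and cDNA reads are not told apart from endogenous transcripts. Another 166 bp of Nfib, merged from exons and held under a joined name (mean 428), had -0.81 ± 0.43 in 16T, -1.09 ± 0.43 in KP1 and 0.52 ± 0.43 in KP22 in the authors' deposited table, with adjusted p of 0.118, 0.0358 and 0.391. Of the other NFI genes, Nfia rose in 16T (0.72 ± 0.13) and fell in KP22 (-0.56 ± 0.14), while Nfix fell in 16T (-0.35 ± 0.056) and rose in KP22 (1.04 ± 0.06), per the authors' deposited table. Nfic rose in KP1 (0.19 ± 0.048) and in KP22 (0.32 ± 0.049) in the authors' deposited table. Of these 3 NFI genes, 1 rose and 1 fell in 16T, 1 and 0 in KP1, and 2 and 1 in KP22. Counts for the NFI genes adjusted over the list alone were 1 and 1, 1 and 0, and 2 and 1, and the camera test gave adjusted p of 0.938, 0.726 and 0.0822.

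In 16T with the Nfib shRNA the largest rises were in C3, which encodes complement component C3, and in Cdh1, which encodes E-cadherin. Their log2 fold changes in the authors' deposited table were 4.88 ± 0.30 (adjusted p = 2.7e-56) and 4.83 ± 0.13, at mean normalized counts of 201 and 8555. Th, the rate-limiting enzyme of catecholamine synthesis, rose by 3.88 ± 0.19 in the authors' deposited table (adjusted p = 2.16e-90). The other large rises in the authors' deposited table were Pla2g2f (3.53 ± 0.35), F5 (3.52 ± 0.24), Cacna2d4 (3.51 ± 0.38), Nptx1 (3.50 ± 0.11), and Piezo2 (3.36 ± 0.13). They encode a secreted phospholipase, coagulation factor V, a calcium channel subunit, a neuronal pentraxin and a mechanosensitive channel. Vwa2, which encodes a protein with von Willebrand factor A domains, had the largest fall among the named genes, -3.05 ± 0.17 in the authors' deposited table (adjusted p = 1.11e-70). It was followed in the authors' deposited table by Ermap (-2.71 ± 0.52), Ces5a (-2.52 ± 0.26), Grp (-2.46 ± 0.32), Sema3c (-2.42 ± 0.10), Arhgap28 (-2.16 ± 0.17), Eya2 (-2.14 ± 0.10), and Arpp21 (-2.08 ± 0.20). Grp encodes the neuropeptide gastrin-releasing peptide, Sema3c a secreted semaphorin and Eya2 a transcriptional coactivator, and the SE of Ermap is close to the largest SE of any feature (0.521). In total 6574 of 14504 tested genes changed, 2907 higher and 3667 lower, and the median size of the changes was 0.40. Changes of at least 1 on the log2 scale numbered 923, of which 545 were rises and 378 falls. With effects recentred on the median gene, all changes were 3509 rises and 3014 falls, so which direction was more frequent depends on the centring. The authors' own test against a change of 0.5 called 813 genes.

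Genes of hypoxia and glycolysis rose as a group in 16T. Of 35 measured, 33 rose and 0 fell (33 and 0 adjusted over the list alone), with a median of 1.29 and a camera adjusted p of 1.53e-167. They included Ankrd37 (2.77 ± 0.14), Bnip3 (2.71 ± 0.058), P4ha2 (2.60 ± 0.10), and Slc16a3 (2.40 ± 0.065) in the authors' deposited table. Of these, Bnip3 is a mitophagy receptor, P4ha2 a collagen prolyl hydroxylase and Slc16a3 a lactate transporter. Of 48 oxidative phosphorylation genes, 1 rose and 29 fell (1 and 30 adjusted over the list alone), with a median of -0.20 (adjusted p = 1.41e-05). Examples in the authors' deposited table were Ndufa4 (-0.68 ± 0.045), Cycs (-0.67 ± 0.049), Uqcrq (-0.60 ± 0.087), and Cox7a2 (-0.58 ± 0.088). Of 45 S phase and E2F target genes, 3 rose and 30 fell (3 and 32 adjusted over the list alone), with a median of -0.20 (adjusted p = 3.44e-05). Falls in the authors' deposited table included Orc1 (-0.61 ± 0.13), Tk1 (-0.51 ± 0.079), and Mcm5 (-0.49 ± 0.036), whereas the repressor E2f8 rose (0.58 ± 0.061). G2/M and mitosis genes had no call: of 42, 14 rose and 6 fell (14 and 6 adjusted over the list alone), with an adjusted p of 0.449. Among its named members Birc5 fell (-0.40 ± 0.10) and Pttg1 rose (0.45 ± 0.11) in the authors' deposited table.

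Neuroendocrine and secretory genes also rose in 16T. Of 36 neuroendocrine identity genes, 21 rose and 8 fell (21 and 8 adjusted over the list alone), with a median of 0.27 (adjusted p = 1.79e-13). The receptor kinase gene Ret rose the most of these in the authors' deposited table (2.91 ± 0.14), followed by the granule genes Scg2 (2.12 ± 0.05) and Pcsk2 (1.52 ± 0.067), whereas Grp fell as given above. Of 35 synaptic vesicle and exocytosis genes, 21 rose and 7 fell (21 and 8 adjusted over the list alone), with a median of 0.38 (adjusted p = 3.96e-10). In the authors' deposited table they included Stx1a (2.74 ± 0.32), Syt7 (1.94 ± 0.044), Slc18a1 (1.79 ± 0.11), and Syt5 (1.59 ± 0.14). Stx1a encodes a syntaxin and Slc18a1 a vesicular monoamine transporter. Of 40 neurotransmitter receptor and ion channel genes, 16 rose and 9 fell (16 and 9 adjusted over the list alone), with an adjusted p of 0.00914, or 0.126 with an inter-gene correlation of 0.05 in place of 0.01. The nicotinic receptor genes Chrnb4 and Chrna3, neighbors on chromosome 9, rose in the authors' deposited table (2.73 ± 0.18 and 2.05 ± 0.17), as did Kcnip1 (1.36 ± 0.38), and Kcnq3 (-1.26 ± 0.22) fell. Of 28 immediate early genes, 15 rose and 4 fell (15 and 4 adjusted over the list alone), with a median of 0.41 (adjusted p = 0.00045). They included Egr1 (1.58 ± 0.11), Dusp6 (1.44 ± 0.10), Fos (1.35 ± 0.12), and Klf6 (1.27 ± 0.069) in the authors' deposited table. Of 31 genes of the unfolded protein and integrated stress responses, 16 rose and 5 fell (16 and 5 adjusted over the list alone) (adjusted p = 0.00169). Rises included Vldlr (1.71 ± 0.13), Trib3 (1.64 ± 0.09), Ddit3 (0.82 ± 0.15), and Herpud1 (0.65 ± 0.07) in the authors' deposited table. Neither neuronal adhesion nor cholesterol synthesis had a call. Of 45 neuronal adhesion and synapse organisation genes, 9 rose and 13 fell (9 and 13 adjusted over the list alone), with an adjusted p of 0.917. Of 33 cholesterol and fatty acid synthesis genes, 14 rose and 7 fell (15 and 9 adjusted over the list alone), with an adjusted p of 0.262. With the log2 fold change in place of the Wald statistic, S phase, oxidative phosphorylation and neurotransmitter receptor genes had adjusted p of 0.128, 0.0606 and 0.224, and mesenchymal transition genes and leukocyte markers, with no call on the Wald statistic, had 0.0367 and 0.0417. With ranks of the Wald statistic, neurotransmitter receptor genes had 0.136.

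In KP1 with the Nfib shRNA the largest rises in the authors' deposited table were Notum (4.86 ± 0.20), Tgm2 (4.72 ± 0.30), Vwa5b1 (4.42 ± 0.074), and Npy1r (3.77 ± 0.12). Notum encodes a carboxylesterase that inactivates Wnt proteins, Tgm2 a transglutaminase and Npy1r a neuropeptide Y receptor. Chrnb4 and Chrna3 followed in the authors' deposited table (3.71 ± 0.29 and 3.58 ± 0.22), with the ephrin receptor gene Epha2 (3.62 ± 0.23) and with Cpne7 (3.59 ± 0.12). The urea transporter gene Slc14a1 fell by 3.89 ± 0.20 in the authors' deposited table (adjusted p = 1.4e-81). Eya2 fell by 3.63 ± 0.12 (adjusted p = 2.5e-198), and the vitamin D receptor gene Vdr had -3.43 ± 0.31 in the authors' deposited table. Further falls in the authors' deposited table were Eda2r (-3.43 ± 0.25), Pde3a (-3.25 ± 0.19), Sphkap (-3.20 ± 0.15), Ephb1 (-3.10 ± 0.12), and Lrrc4 (-2.95 ± 0.29). They encode an ectodysplasin receptor, a phosphodiesterase, a kinase anchoring protein, an ephrin receptor and a synaptic adhesion protein. In total 5402 of 14504 tested genes changed, 2558 higher and 2844 lower, with a median size of 0.38. Recentred on the median gene, 2829 were higher and 2603 lower. Of the changed genes, 864 changed by at least 1 on the log2 scale, and the test against 0.5 called 709. With a t distribution of 6 degrees of freedom in place of the normal one, 3301 genes were called.

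Neuroendocrine identity genes rose in KP1, whereas genes of hypoxia and of lipid synthesis fell. Of 36 neuroendocrine genes, 23 rose and 7 fell (24 and 7 adjusted over the list alone), with a median of 0.25 (adjusted p = 5.14e-10). Among them were Ret (1.22 ± 0.081), Calcb (1.20 ± 0.43), Pcsk2 (1.03 ± 0.066), and Ddc (1.02 ± 0.036) in the authors' deposited table. Of 35 hypoxia and glycolysis genes, 0 rose and 18 fell (1 and 20 adjusted over the list alone), with a median of -0.20 (adjusted p = 0.000168). The falls in the authors' deposited table included Hk2 (-0.79 ± 0.095), Pfkfb3 (-0.75 ± 0.063), P4ha2 (-0.52 ± 0.09), and Kdm3a (-0.48 ± 0.044). Of 33 cholesterol and fatty acid synthesis genes, 0 rose and 21 fell (1 and 22 adjusted over the list alone), with a median of -0.22 (adjusted p = 2.23e-05). They included Scd1 (-0.68 ± 0.20), Cyp51 (-0.61 ± 0.059), Stard4 (-0.52 ± 0.068), and Nsdhl (-0.50 ± 0.089) in the authors' deposited table. These 3 calls held with a correlation of 0.05, while the following 6 did not. Of 35 synaptic vesicle genes, 16 rose and 7 fell (16 and 7 adjusted over the list alone) (adjusted p = 0.00147, or 0.0585 with a correlation of 0.05). In the authors' deposited table Rab3b (1.27 ± 0.13), Ptprn2 (1.11 ± 0.05), and Syt13 (1.08 ± 0.10) rose and Rph3a (-1.39 ± 0.35) fell. Of 42 G2/M genes, 19 rose and 1 fell (21 and 1 adjusted over the list alone), with a median of 0.11 (adjusted p = 0.00172, or 0.0728). The rises in the authors' deposited table included Prc1 (0.31 ± 0.045), Kif4 (0.29 ± 0.048), Ccnb2 (0.28 ± 0.057), and Ube2c (0.28 ± 0.041). Of 31 stress response genes, 15 rose and 2 fell (15 and 2 adjusted over the list alone) (adjusted p = 0.00567, or 0.0921), and Sesn2 (0.44 ± 0.085) was an example in the authors' deposited table.

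Of 40 neurotransmitter receptor and ion channel genes in KP1, 13 rose and 8 fell (13 and 9 adjusted over the list alone) (adjusted p = 0.00567, or 0.105 with a correlation of 0.05). Beside the nicotinic genes, which rose, Gabra2 (-2.16 ± 0.45) fell in the authors' deposited table. Of 45 neuronal adhesion genes, 9 rose and 16 fell (10 and 16 adjusted over the list alone) (adjusted p = 0.0221, or 0.192). The cell surface genes Opcml (-2.54 ± 0.16), Pcdh19 (-2.50 ± 0.10), Cdh6 (-2.36 ± 0.28), and Cdh11 (-1.93 ± 0.10) fell in the authors' deposited table. Of 28 immediate early genes, 14 rose and 4 fell (14 and 7 adjusted over the list alone) (adjusted p = 0.0378, or 0.192). Rises in the authors' deposited table included Spry4 (1.45 ± 0.43), Spry2 (1.39 ± 0.13), Egr2 (1.05 ± 0.37), and Egr1 (0.95 ± 0.10). The S phase and oxidative phosphorylation lists had no call on the Wald statistic. Of 45 S phase genes, 16 rose and 8 fell (19 and 9 adjusted over the list alone), and of 48 oxidative phosphorylation genes, 15 rose and 8 fell (17 and 8 adjusted over the list alone), both with an adjusted p of 0.128; with ranks, oxidative phosphorylation genes were called as higher (adjusted p = 0.023). Cyclin E genes rose in the authors' deposited table (Ccne2 (0.53 ± 0.056) and Ccne1 (0.46 ± 0.062)), as did Cox7a2 (0.74 ± 0.088). With the log2 fold change as the statistic, the hypoxia, cholesterol, synaptic vesicle, stress response and immediate early lists each had an adjusted p of 0.175. The neurotransmitter receptor and G2/M lists had 0.196 and 0.268, and 0.0269 remained for the neuroendocrine and neuronal adhesion lists. With ranks, neurotransmitter receptor, neuronal adhesion and immediate early genes had 0.503, 0.454 and 0.117.

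In KP22 with Nfib cDNA the largest rises in the authors' deposited table were Prrg3 (4.97 ± 0.14), Isl1 (4.94 ± 0.24), Trp73 (4.75 ± 0.18), and Fam124a (4.68 ± 0.38). Isl1 encodes a LIM homeodomain transcription factor of neuroendocrine cells and Trp73 the p53 relative p73. They were followed in the authors' deposited table by Lrrn1 (4.50 ± 0.23), Necab2 (4.26 ± 0.14), Nr2f1 (4.19 ± 0.17), and Tll1 (4.17 ± 0.23), of which Nr2f1 encodes a nuclear receptor and Tll1 an extracellular protease. Pck1, an enzyme of gluconeogenesis, fell by 7.86 ± 0.44 in the authors' deposited table (adjusted p = 5.91e-69), the largest change among the named genes. Further falls in the authors' deposited table were Vstm2b (-7.32 ± 0.43), Emx1 (-6.73 ± 0.44), Ccbe1 (-5.46 ± 0.43), and Frem1 (-5.42 ± 0.27), Emx1 being a homeobox gene and Frem1 an extracellular matrix gene. The acyl-CoA synthetase gene Acsf2 (-4.91 ± 0.20), the glutamate receptor gene Gria4 (-4.80 ± 0.32) and the metalloprotease gene Adamts9 (-4.78 ± 0.20) fell as well in the authors' deposited table. In total 6730 of 17544 tested genes changed, 3423 higher and 3307 lower, with a median size of 0.45. The balance of directions turned to 2838 higher and 3810 lower when recentred on the median gene, and to 2244 and 2277 with a t distribution of 6 degrees of freedom. Of the 1416 that changed by at least 1, 505 rose and 911 fell, and the test against 0.5 called 1264.

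Neuroendocrine and vesicle genes fell in KP22 with Nfib cDNA and cell cycle genes rose. Of 36 neuroendocrine identity genes, 8 rose and 20 fell (9 and 20 adjusted over the list alone), with a median of -0.26 (adjusted p = 5.03e-14). The granule protein genes Chgb (-4.27 ± 0.059), Scg2 (-3.23 ± 0.089), and Resp18 (-2.74 ± 0.089) were among the falls in the authors' deposited table, whereas Isl1, of the same list, rose as given above. Of 35 synaptic vesicle genes, 7 rose and 20 fell (7 and 20 adjusted over the list alone), with a median of -0.36 (adjusted p = 3.54e-07). The falls in the authors' deposited table included Rab3b (-2.64 ± 0.15), Ptprn (-2.40 ± 0.05), Stx1a (-2.26 ± 0.22), and Unc13b (-1.93 ± 0.09). Of 45 S phase genes, 35 rose and 1 fell (37 and 1 adjusted over the list alone), with a median of 0.33 (adjusted p = 5.23e-11). Of 42 G2/M genes, 36 rose and 1 fell (36 and 1 adjusted over the list alone), with a median of 0.28 (adjusted p = 3.25e-08). Examples in the authors' deposited table were E2f2 (1.20 ± 0.046), Mcm10 (0.61 ± 0.078), Rrm2 (0.57 ± 0.041), and Gins3 (0.54 ± 0.12) for S phase and Mybl2 (0.70 ± 0.061), Foxm1 (0.53 ± 0.068), Mki67 (0.48 ± 0.045), and Kif2c (0.46 ± 0.051) for mitosis. Of 35 hypoxia and glycolysis genes, 4 rose and 23 fell (6 and 23 adjusted over the list alone), with a median of -0.31 (adjusted p = 3.2e-06). Among these were P4ha2 (-1.01 ± 0.10), P4ha1 (-0.92 ± 0.056), and Pfkfb4 (-0.76 ± 0.12) in the authors' deposited table. Of 33 cholesterol and fatty acid synthesis genes, 18 rose and 7 fell (18 and 7 adjusted over the list alone) (adjusted p = 0.00767, or 0.108 with a correlation of 0.05). The sterol genes Mvd (0.90 ± 0.073), Hmgcs1 (0.82 ± 0.046), and Hsd17b7 (0.77 ± 0.086) rose in the authors' deposited table and Acss2 (-2.07 ± 0.09), an acetyl-CoA synthetase, fell.

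Neurotransmitter receptor, neuronal adhesion and stress response genes had no call in KP22. Of 40 neurotransmitter receptor genes, 13 rose and 14 fell (13 and 15 adjusted over the list alone), and of 45 neuronal adhesion genes, 15 rose and 7 fell (15 and 8 adjusted over the list alone). Of 31 stress response genes, 12 rose and 10 fell (12 and 10 adjusted over the list alone). The adjusted p of these 3 lists were 0.216, 0.53 and 0.284, and in the test of the difference between the knockdown lines and KP22 they were 0.525, 0.59 and 0.000559. Single members moved far in the authors' deposited table, such as Clstn2 (-3.45 ± 0.14), Cdh6 (2.82 ± 0.33), Dlgap1 (-2.07 ± 0.41), and Vldlr (-2.60 ± 0.37). Of 28 immediate early genes, 11 rose and 8 fell (11 and 9 adjusted over the list alone), with a median of 0.36, a mean of -0.12 and a test direction of lower (adjusted p = 0.693), so the median and the test differ in sign. The falls of Egr1 (-3.37 ± 0.13), Fos (-2.44 ± 0.13), Egr4 (-1.73 ± 0.40), and Fosb (-1.25 ± 0.20) in the authors' deposited table were large. Of 48 oxidative phosphorylation genes, 0 rose and 11 fell (0 and 10 adjusted over the list alone) (adjusted p = 0.288, or 0.0135 with ranks of the Wald statistic), with Cox7b (-0.38 ± 0.074) and Atp5e (-0.30 ± 0.06) in the authors' deposited table. With the log2 fold change as the statistic, the G2/M, hypoxia and cholesterol lists had adjusted p of 0.072, 0.211 and 0.295, and Notch and YAP and interferon-stimulated genes, with no call on the Wald statistic, had 0.0259 and 0.0246.

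**Figure D1:**
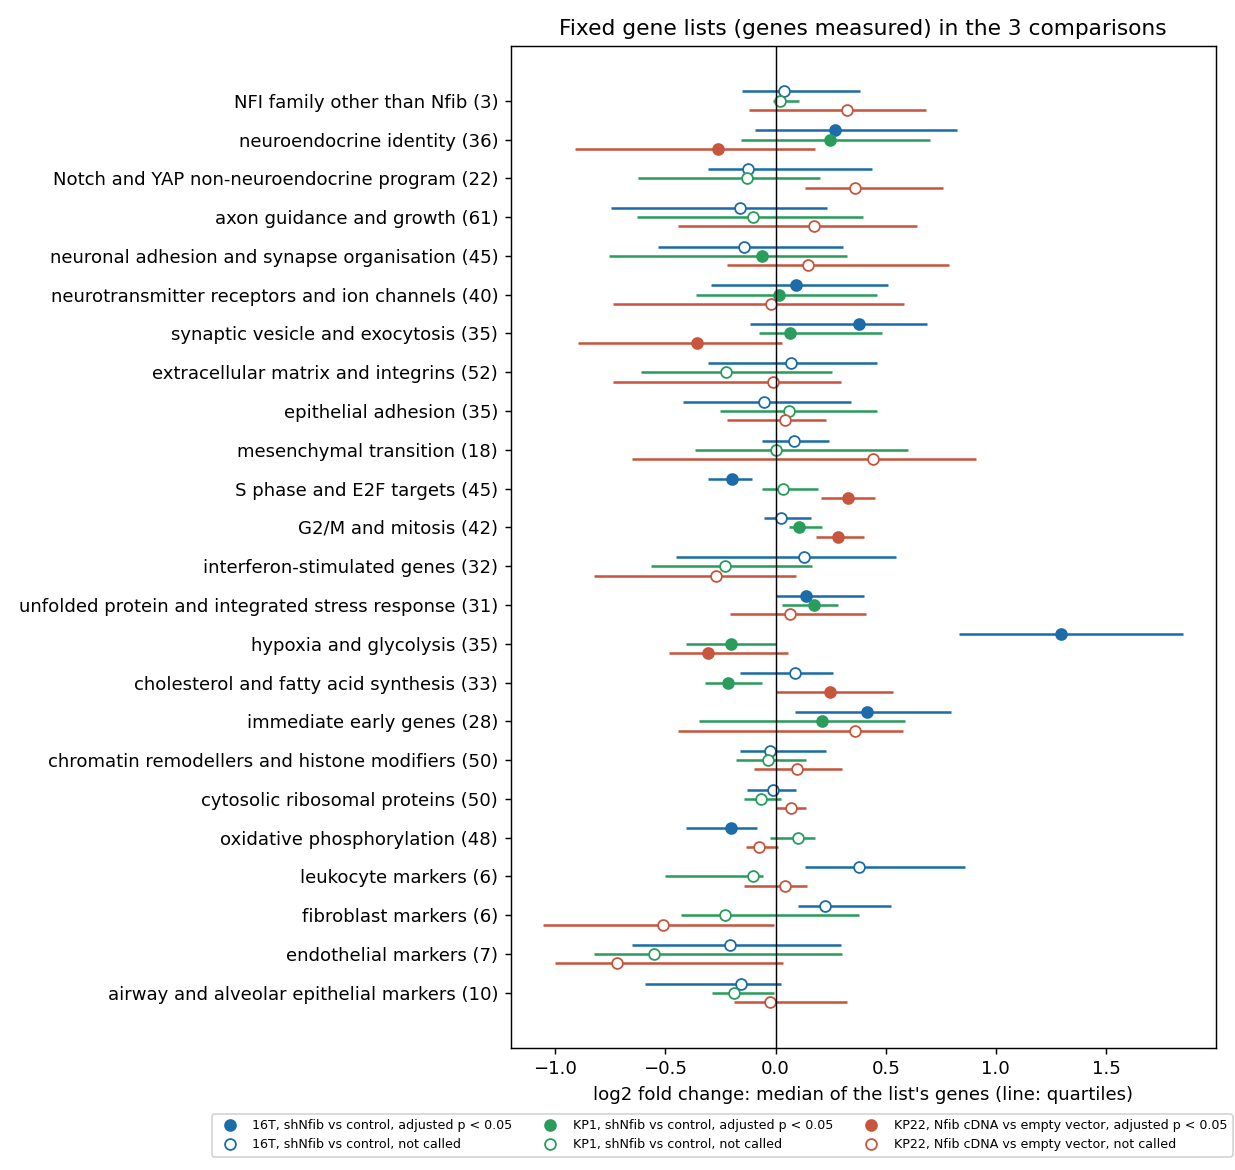
Median log2 fold change of the measured genes of 24 gene lists (points, filled where the camera adjusted p was below 0.05) with lower and upper quartiles (lines) in 16T, KP1 and KP22. Hypoxia and glycolysis genes had medians of 1.29 in 16T, -0.20 in KP1 and -0.31 in KP22, and neuroendocrine identity genes 0.27, 0.25 and -0.26.

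In KP22, neighboring genes on chromosome 2 fell together, a region singled out after its values were seen. Between 148681120 and 156392979 (mm10), 84 genes with a mean of at least 100 had a median of -0.48, with quartiles of -0.67 and -0.26. Of these genes 68 fell and 3 rose, while 927 other genes of chromosome 2 had a median of 0.041. In 16T and KP1 the medians of the same 84 genes were -0.040 and -0.062. The region holds Gins1 of the S phase list, which had -0.35 ± 0.13 in the authors' deposited table. Without the region, 6655 genes changed in KP22.

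**Figure D2:**
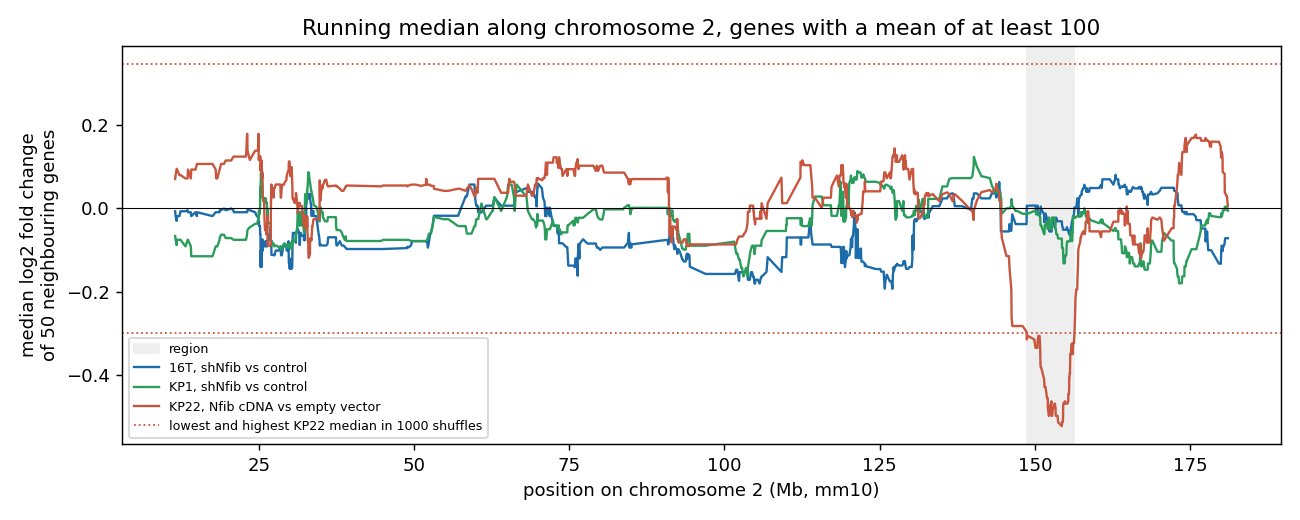
Running median of the log2 fold change of 50 neighboring genes along chromosome 2 (position in Mb, mm10) in the 3 comparisons, with the region shaded and the lowest and highest KP22 medians of 1000 shuffled gene orders dotted (-0.30 and 0.35). The KP22 line reaches -0.52 inside the region, whose genes had medians of -0.040 in 16T and -0.062 in KP1.

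Several lists held changed genes but had no camera call on the Wald statistic in any of the 3 lines. Of all tested genes 45.3% were called in 16T, 37.2% in KP1 and 38.4% in KP22, so many members of any list would be called. Of 61 axon guidance and growth genes, 18 rose and 25 fell in 16T, 21 and 25 in KP1, and 22 and 21 in KP22. Axon guidance gene counts adjusted over the list alone were 20 and 26, 21 and 25, and 23 and 21, and adjusted p were 0.386, 0.101 and 0.149. In the authors' deposited table these included Sema3c (-2.42 ± 0.10), Unc5c (-1.54 ± 0.25), Plxnd1 (1.35 ± 0.089), and Sema5a (-1.30 ± 0.37) in 16T, Ephb1 (-3.10 ± 0.12), Sema6a (-1.94 ± 0.12), and Stmn2 (-1.88 ± 0.20) in KP1, and Ntn1 (3.04 ± 0.18), Unc5d (3.03 ± 0.37), and Epha4 (2.82 ± 0.21) in KP22. Of 52 extracellular matrix and integrin genes, 16 rose and 11 fell in 16T, 11 and 14 in KP1, and 9 and 18 in KP22. Matrix and integrin gene counts adjusted over the list alone were 18 and 12, 12 and 15, and 9 and 18, and adjusted p were 0.449, 0.124 and 0.216. Thbs1, which encodes thrombospondin, rose in 16T (2.18 ± 0.07) and in KP1 (0.95 ± 0.065) and fell in KP22 (-3.09 ± 0.092) in the authors' deposited table, and Vcan (-2.43 ± 0.085) fell in KP1. Of 35 epithelial adhesion genes, 8 rose and 8 fell in 16T, 11 and 8 in KP1, and 13 and 6 in KP22. Epithelial gene counts adjusted over the list alone were 8 and 8, 11 and 8, and 13 and 6, and adjusted p were 0.31, 0.931 and 0.635. The desmosome gene Dsp fell in 16T (-1.37 ± 0.10) and KP1 (-1.58 ± 0.051) and rose in KP22 (0.61 ± 0.046) in the authors' deposited table, whereas Cdh1 rose in all 3 lines (4.83 ± 0.13, 1.20 ± 0.068 and 0.22 ± 0.059). Of 18 mesenchymal transition genes, 4 rose and 0 fell in 16T, 5 and 5 in KP1, and 6 and 4 in KP22. Mesenchymal gene counts adjusted over the list alone were 3 and 0, 5 and 5, and 6 and 4, and adjusted p were 0.449, 0.688 and 0.223. Examples in the authors' deposited table were Lox (3.23 ± 0.20) in 16T, Vim (-2.17 ± 0.18) in KP1, and Twist1 (3.88 ± 0.27), Zeb1 (-1.63 ± 0.26), and Snai2 (1.54 ± 0.22) in KP22.

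Of 22 genes of a Notch and YAP program of non-neuroendocrine cells, 5 rose and 3 fell in 16T, 5 and 5 in KP1, and 8 and 2 in KP22. Notch and YAP gene counts adjusted over the list alone were 5 and 2, 5 and 5, and 8 and 2, and adjusted p were 0.75, 0.759 and 0.0538. The authors' deposited table gave Egfr (1.90 ± 0.37), Epha2 (1.69 ± 0.16), and Hes1 (1.15 ± 0.29) in 16T, Sox9 (-1.73 ± 0.17) and Tead2 (-1.37 ± 0.41) in KP1, and Heyl (3.19 ± 0.22), Tead2 (2.52 ± 0.41), and Egfr (-1.94 ± 0.46) in KP22. Of 32 interferon-stimulated genes, 9 rose and 6 fell in 16T, 3 and 8 in KP1, and 2 and 10 in KP22. Interferon-stimulated gene counts adjusted over the list alone were 9 and 6, 3 and 9, and 2 and 11, and adjusted p were 0.656, 0.347 and 0.0895, the last being 0.0135 (lower) with ranks. Usp18 rose in 16T (1.76 ± 0.23) and KP1 (0.56 ± 0.22) and fell in KP22 (-2.55 ± 0.34) in the authors' deposited table. Of 50 chromatin remodeller and histone modifier genes, 16 rose and 17 fell in 16T, 13 and 19 in KP1, and 21 and 13 in KP22. Chromatin gene counts adjusted over the list alone were 16 and 17, 14 and 20, and 23 and 13, and adjusted p were 0.656, 0.876 and 0.164. The remodeller gene Smarca1 rose in 16T (1.97 ± 0.12) and fell in KP22 (-0.70 ± 0.17) in the authors' deposited table, and Chd3 (0.87 ± 0.046) and Chd5 (0.65 ± 0.069) rose in KP1. Of 50 cytosolic ribosomal protein genes, 10 rose and 16 fell in 16T, 3 and 19 in KP1, and 15 and 6 in KP22. Ribosomal gene counts adjusted over the list alone were 10 and 16, 4 and 19, and 15 and 6, and adjusted p were 0.812, 0.0979 and 0.149; with ranks the list was lower in KP1 (0.0356) and higher in KP22 (0.0306). Changes in the authors' deposited table included Rps2 (-0.45 ± 0.045) in 16T, Rpl4 (-0.60 ± 0.051) in KP1 and Rps20 (0.41 ± 0.034) in KP22. The median, mean and test differed in sign for Notch and YAP genes in 16T and KP1, for neuronal adhesion, epithelial adhesion and chromatin genes in 16T, and for mesenchymal genes in KP1.

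Markers of other cell types that a tumor line could hold were few at a mean of at least 10. Of 6 leukocyte markers, 0 rose and 1 fell in 16T, 0 and 1 in KP1, and 1 and 0 in KP22. Of 6 fibroblast markers, 3 rose and 1 fell in 16T, 0 and 2 in KP1, and 0 and 3 in KP22. Of 7 endothelial markers, 1 rose and 1 fell in 16T, 2 and 1 in KP1, and 0 and 4 in KP22. Of 10 airway and alveolar markers, 1 rose and 4 fell in 16T, 1 and 3 in KP1, and 0 and 2 in KP22. In 16T, KP1 and KP22 the counts adjusted over the list alone were 1 and 1, 0 and 2, and 1 and 0 for leukocytes and 3 and 1, 0 and 2, and 0 and 3 for fibroblasts. They were 1 and 1, 2 and 2, and 0 and 4 for endothelium and 1 and 4, 1 and 3, and 0 and 2 for airway. The adjusted p were 0.812, 0.637 and 0.781 for leukocytes and 0.75, 0.637 and 0.53 for fibroblasts. For endothelium they were 0.812, 0.931 and 0.149, and for airway, whose median and mean differed in sign in KP22, 0.917, 0.557 and 0.829. The B cell receptor gene Cd79a fell in 16T (-0.63 ± 0.14) and KP1 (-0.63 ± 0.15) and rose in KP22 (1.05 ± 0.21) in the authors' deposited table. The endothelial receptor gene Kdr fell in all 3 lines (-1.48 ± 0.18, -1.62 ± 0.21 and -1.76 ± 0.16) in the authors' deposited table, and the surfactant gene Sftpc (-2.07 ± 0.25) fell in 16T.

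Across the 3 lines, 1464 genes moved with or against the level of Nfib throughout: 773 fell with the shRNA in both lines and rose with the cDNA, and 691 did the reverse. They made up 66.8% of the 2193 genes called in all 3, of 14504 tested in all. The coactivator gene Eya2 on chromosome 2 (165595028 to 165771727, mm10) had -2.14 ± 0.10 in 16T, -3.63 ± 0.12 in KP1 and 2.31 ± 0.23 in KP22 in the authors' deposited table. In the same order the authors' deposited table gave -2.08 ± 0.20, -2.40 ± 0.21 and 2.14 ± 0.24 for Arpp21, and -1.96 ± 0.20, -3.43 ± 0.25 and 2.99 ± 0.41 for Eda2r. The Notch ligand gene Dll4 followed Nfib as well in the authors' deposited table (-1.51 ± 0.075, -1.51 ± 0.075 and 2.38 ± 0.087). Pkp1, which encodes a desmosomal plakophilin, had -1.71 ± 0.12, -1.82 ± 0.23 and 3.98 ± 0.12 in the authors' deposited table, and the endocytic receptor gene Lrp2 -1.49 ± 0.34, -2.56 ± 0.27 and 4.13 ± 0.43. Thsd7b, Crybb1, Fgfrl1, Rmst, Pdzrn4, Lrrc4, Fam19a5, Xdh and Tmem178 were the others named by the rule.

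The genes that moved against Nfib in all 3 lines included Th, with 3.88 ± 0.19 in 16T, 1.88 ± 0.10 in KP1 and -3.09 ± 0.12 in KP22 in the authors' deposited table. The nicotinic receptor genes Chrna3 (55011343 to 55026559) and Chrnb4 (55028156 to 55048544), next to each other on chromosome 9 of mm10, had -2.99 ± 0.30 and -1.88 ± 0.26 in KP22 in the authors' deposited table, against rises in both knockdown lines given above. Car8 had 3.19 ± 0.12, 2.57 ± 0.12 and -2.74 ± 0.18, and the Ras exchange factor gene Rasgrf2 2.84 ± 0.26, 2.34 ± 0.23 and -2.38 ± 0.39, in the authors' deposited table. Antxr1, F5, Cox6a2, Nxph3 and Epha2 completed those named by the rule, of which Antxr1, Cox6a2 and Nxph3 had means of 69.5, 74.4 and 23.7.

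**Figure D3:**
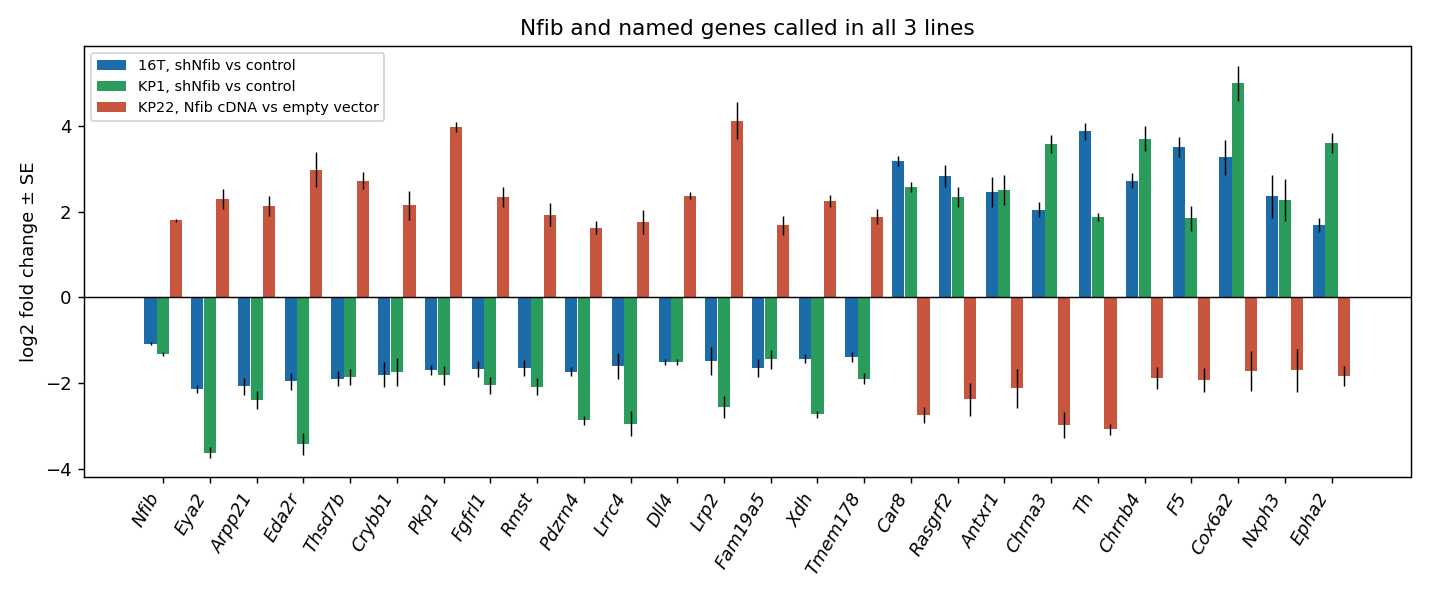
Log2 fold change of Nfib, of 15 named genes that followed Nfib and of 10 that moved against it, in 16T and KP1 (shRNA against control) and in KP22 (cDNA against empty vector); bars start at 0 and error bars are SEs of the authors' fit. Eya2 fell by 3.63 in KP1 and rose by 2.31 in KP22, and Th had 3.88 in 16T and -3.09 in KP22, per the authors' deposited table.

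The overlaps of changed genes were larger in the direction of Nfib than independent sets of the same sizes would give, by Fisher's exact test on genes tested in both comparisons, adjusted over 16 overlaps. Genes that rose in both 16T and KP1 numbered 1259 against 513 for independent sets (adjusted p = 2.21e-305). Genes that fell in both numbered 1434 against 719 (adjusted p = 5.67e-234). Genes that rose in 16T and fell in KP22 numbered 1333 against 628, and those that fell in 16T and rose in KP22 1516 against 846. The same overlaps of KP1 with KP22 held 1086 genes against 553 and 1155 against 656. Overlaps in the same direction in 16T and KP22 were smaller than independent sets would give, 435 against 671 for rises and 455 against 792 for falls. Pearson's r of the log2 fold changes across 15008 genes was 0.443 between 16T and KP1, -0.325 between 16T and KP22 and -0.229 between KP1 and KP22. These relations are across genes, and genes are not independent replicates, which also holds for the exact tests. Independent sets also take every gene to be called as readily, whereas SEs were smaller at higher means. The numbers for independent sets are therefore not an exact level for chance. Uneven SEs would raise overlaps in both directions, yet those in the same direction in 16T and KP22 were smaller, as given above. The titles name the same shRNA in 16T and KP1, so their overlap cannot separate lower Nfib from other effects of that shRNA. Of the genes that followed Nfib or moved against it, 826 were left with a t distribution of 6 degrees of freedom and 126 with changes of at least 1 in every line.

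Combining the lines, the mean effect of the shRNA in 16T and KP1 was called for 7019 of 15483 genes, 3128 higher and 3891 lower, or 3664 higher and 3282 lower when recentred on the median gene. The mean of the 3 effects turned towards higher Nfib was called for 7945 of 15008 genes, 4383 higher and 3562 lower, of which 628 changed by at least 1, 276 higher and 352 lower. Recentred on the median gene, the mean of the 3 effects had 3637 higher and 4144 lower. Neuroendocrine identity, synaptic vesicle and hypoxia genes were lower with higher Nfib in this mean, with medians of -0.17, -0.24 and -0.50 and adjusted p of 4.74e-21, 1.27e-11 and 7.56e-37. The hypoxia genes did not move alike in the 3 lines: with the shRNA 33 rose and 0 fell in 16T, whereas 0 rose and 18 fell in KP1, and with the cDNA 4 rose and 23 fell in KP22. S phase genes were higher in the mean, with a median of 0.17 (adjusted p = 1.92e-05, or 0.193 with the log2 fold change as the statistic). In KP1, however, 16 of them rose and 8 fell with the shRNA, with no call. Calls of neurotransmitter receptor, cholesterol synthesis and immediate early genes (adjusted p = 0.00482, 0.0379 and 0.0233) were lost with a correlation of 0.05, at 0.115, 0.24 and 0.17. Axon guidance genes, with no call on the Wald statistic, had an adjusted p of 0.0155 with the log2 fold change as the statistic. In the mean of the knockdown lines, neuroendocrine, synaptic vesicle, hypoxia, immediate early and stress response genes rose (adjusted p = 3.62e-16, 5.4e-09, 4.04e-50, 0.000843 and 0.000627), the hypoxia genes through 16T, as they fell in KP1. Neurotransmitter receptor and G2/M genes (adjusted p = 0.00157 and 0.0304) lost their calls there with a correlation of 0.05, at 0.0596 and 0.257. With the log2 fold change as the statistic, axon guidance genes had an adjusted p of 0.0433 in the mean of the knockdown lines, and with ranks S phase genes had 0.0216 (lower).

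**Figure D4:**
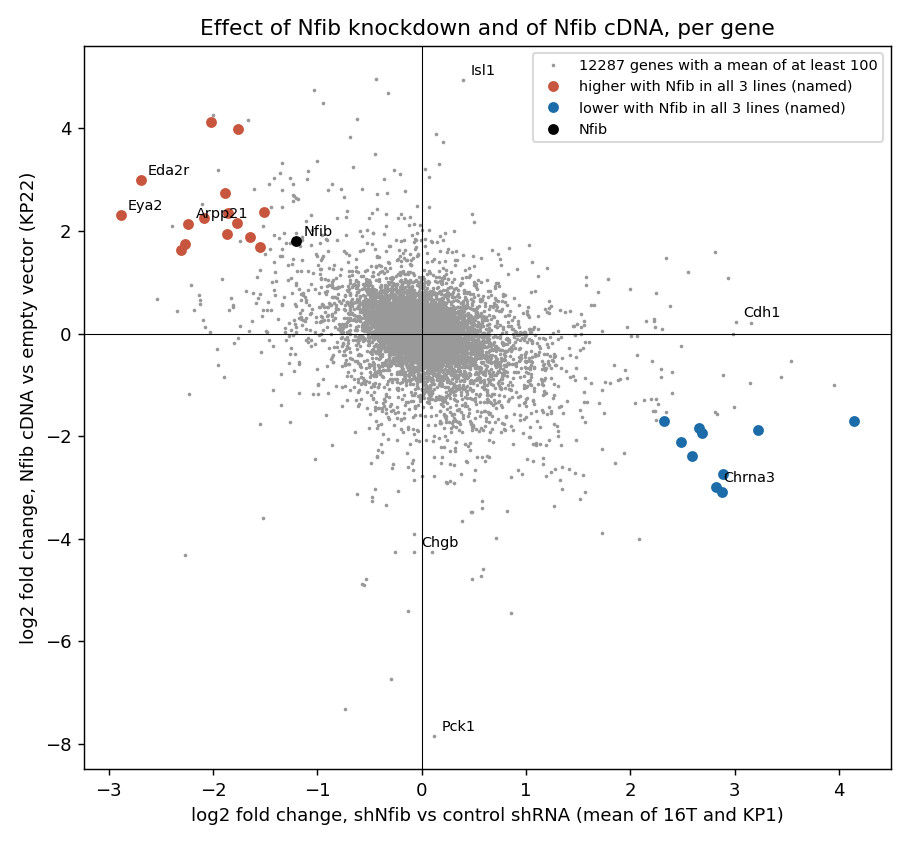
Log2 fold change with the Nfib shRNA (mean of 16T and KP1, horizontal) against that with Nfib cDNA in KP22 (vertical) for 12287 genes with a mean of at least 100, with Nfib and the named genes called in all 3 lines marked, 3 of which have a lower mean. Pearson's r across these 12287 genes was -0.362, Cdh1 lies at the right with 0.22 ± 0.059 in KP22 in the authors' deposited table, and Pck1 lies lowest, at -7.86.

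The effect of the shRNA differed between 16T and KP1 for 4417 of 15008 genes, 2097 with the higher value in 16T and 2320 with the lower, or 2357 and 1999 when recentred on the median gene. Of these genes 788 were called in both lines with the same sign, 659 in both with opposite signs, and 2970 in at most 1 line. Nfib itself differed by 0.24 ± 0.05 in this test (adjusted p = 1.9e-05), and the effects were not scaled by it. The smallest p values belonged to Pkm (difference 1.90 ± 0.039), Aldoa (2.36 ± 0.052), P4ha1 (2.71 ± 0.07), Gpi1 (1.74 ± 0.047), Igfbp5 (1.56 ± 0.043) and Bnip3 (2.86 ± 0.08), in this order. Pkm, Aldoa and Gpi1 encode enzymes of glycolysis, P4ha1 a collagen prolyl hydroxylase and Igfbp5 an insulin-like growth factor binding protein. Of 35 hypoxia and glycolysis genes, 33 were higher and 0 lower in 16T (34 and 0 adjusted over the list alone), with a median difference of 1.55 (adjusted p = 1.67e-236). S phase and oxidative phosphorylation genes had lower values in 16T (medians -0.27 and -0.26, adjusted p = 3.62e-09 and 1.34e-09). Cholesterol synthesis and synaptic vesicle genes had higher ones (0.31 and 0.13, adjusted p = 2.64e-08 and 0.000996). Calls of neuronal adhesion and extracellular matrix genes (adjusted p = 0.0433 and 0.0204) were lost with a correlation of 0.05, at 0.284 and 0.271. With the log2 fold change as the statistic, synaptic vesicle and neuronal adhesion genes had adjusted p of 0.0746 and 0.052 (0.0738 and 0.124 with ranks), and interferon-stimulated genes and leukocyte markers, with no call on the Wald statistic, had 0.0145 and 0.000454. With a t distribution of 6 degrees of freedom 1870 genes differed, 997 higher in 16T and 873 lower, and 779 of the 4417 differed by at least 1, 477 higher and 302 lower.

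Turned towards higher Nfib, the effect in the knockdown lines differed from that in KP22 for 5515 of 15008 genes, 2858 higher in the knockdown lines. Among genes called in both, 965 had log2 fold changes of the same sign with shRNA and with cDNA and 1203 had opposite signs but different sizes. The smallest p values belonged to Chgb, which encodes chromogranin B (difference 4.34 ± 0.071), Eef1a2 (2.83 ± 0.065), Clock (2.47 ± 0.062), Gstm5 (2.77 ± 0.071), Cdh1 (-3.24 ± 0.093) and Acsl1 (-1.89 ± 0.055). Chgb had 0.38 ± 0.057 in 16T, -0.52 ± 0.054 in KP1 and -4.27 ± 0.059 in KP22 in the authors' deposited table, and the elongation factor gene Eef1a2 0.53 ± 0.047, 0.63 ± 0.047 and -3.41 ± 0.056. The circadian gene Clock, with -2.33 ± 0.051 in KP22 in the authors' deposited table, had -0.24 ± 0.051 in 16T and -0.033 ± 0.05 in KP1. G2/M and S phase genes had lower values in the knockdown lines (medians -0.36 and -0.23, adjusted p = 2.43e-14 and 7.76e-08), as had hypoxia and stress response genes (-0.30 and -0.38, adjusted p = 3.7e-08 and 0.000559). Calls of NFI, neuroendocrine, Notch and YAP, interferon and oxidative phosphorylation genes had adjusted p of 0.0319, 0.0224, 0.0214, 0.0409 and 0.0214. They were lost with a correlation of 0.05, at adjusted p of 0.0666, 0.194, 0.124, 0.219 and 0.195. With the log2 fold change as the statistic, S phase and stress response genes had adjusted p of 0.0564 and 0.121, and mesenchymal transition genes and endothelial markers, with no call on the Wald statistic, had 0.0103 and 0.0132. With ranks, immediate early genes had 0.0161 (lower). KP22 was the sole line with cDNA, so line and kind of vector changed together. The effects were not scaled by how far Nfib moved, and Nfib itself differed in this test (-0.60 ± 0.044, adjusted p = 2.83e-40). A gene with an equal response per change of Nfib could therefore be counted as differing. With a t distribution of 6 degrees of freedom 3356 genes differed, and 1254 of the 5515 differed by at least 1.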

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

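The tests of KP1 values, shuffled gene orders, the knockdown effect in the chromosome 2 region, shared signs and the correlation with each knockdown line were chosen only after the results were seen; those of matched random lists, list members outside glycolysis, genes left out of the region search, and trends were chosen before.

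Hypoxia and glycolysis genes had a median of 1.29 in 16T with the Nfib shRNA, and the effect differed from KP1 (adjusted p = 1.67e-236), with differences of log2 fold changes of 1.90 for Pkm, 2.36 for Aldoa, 2.71 for P4ha1, 1.74 for Gpi1 and 2.86 for Bnip3. A response to lower Nfib shared by both lines would raise the list in KP1 too, where its median was -0.20, although Nfib fell there as well. The highest median of 10000 random lists of like mean expression was 0.18 in 16T, which argues against a trend with expression level. Lower oxygen or higher density in the 16T shRNA cultures stays open: members outside glycolysis had a median of 1.27 and glycolysis genes 1.31, which such a cause needs but any activation of the hypoxia pathway would also give. It may also be a response to Nfib found in 16T and not in KP1. In KP22 with Nfib cDNA 4 of the genes rose and 23 fell, the direction such a response would give (median -0.31, camera adjusted p = 3.2e-06, or 0.211 with the log2 fold change as the statistic). There glycolysis genes had a median of -0.38 (3 of 18 above 0) and the other members -0.11 (7 of 17 above 0). The 2 explanations cannot be told apart, since the labels give no culture conditions per sample.

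In KP22 with Nfib cDNA, 84 genes between 148681120 and 156392979 of chromosome 2 had a median of -0.48, a run noticed in the data. The lowest median of 50 neighbors in 1000 shuffled gene orders was -0.30 against -0.52 observed, which argues against a chance run of independent genes. Shuffling removes any likeness between neighboring genes, so it cannot exclude that such likeness contributed. Runs in 16T also lay below every shuffle, but by less (-0.312 against -0.302 for the lowest). A response to Nfib shared with the knockdown lines would raise the same genes there, where the median of the mean knockdown effect was -0.065. A copy-number difference between the KP22 cultures could lower the region. Of 17 genes with a mean of 10 to 100, which had no part in the search, 41.2% were below 0. The exact 95% interval was 18.4% to 67.1%. The share is under the limit set beforehand to count against copy number, although that limit took no account of the interval. Of 193 other genes of chromosome 2 with such means, 44.0% were below 0. The 17 genes thus gave no sign of a copy-number loss. They are too few and too noisy to exclude one, as the median SE in KP22 at such means was 0.468. Copy number and regional regulation cannot be told apart for the genes of the region with the values at hand.

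Effects of the shRNA and of the cDNA opposed each other across genes, with a rank correlation of -0.328 over 14277 genes that have a GC value. With ranks of mean expression, exon length and GC content removed, the correlation across genes stayed at -0.325. This could hardly differ, as the effects in 16T, KP1 and KP22 had rank correlations with these traits only between -0.0595 and 0.0571. It argues against such trends only in the values as the authors normalized them. In all 3 lines, 328 called genes had 1 sign and 1464 opposed it with the level of Nfib. These counts cannot test a response to carrying a vector, since the controls carried one too and it would cancel within each comparison. They could speak to handling only if it differed between the groups in the same direction in all 3 lines, which is not known. The correlation with KP22 was -0.229 for the knockdown line with the weaker one, which restates the pattern and decides nothing about a response to the level of Nfib. Such a response stays open and without a test of its own here, as does the authors' normalization, which could not be varied.

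Other results drew attention because the test of the difference itself passed. The effect of the shRNA differed between 16T and KP1 for 4417 genes, among them Igfbp5 by 1.56. It also differed for S phase (adjusted p = 3.62e-09), oxidative phosphorylation (1.34e-09), cholesterol synthesis (2.64e-08), synaptic vesicle (0.000996), extracellular matrix (0.0204) and neuronal adhesion genes (0.0433), of which neuronal adhesion and extracellular matrix lost their calls with a correlation of 0.05. The effect turned towards higher Nfib, not scaled by how far Nfib itself moved, differed between the knockdown lines and KP22 for 5515 genes. Among these the differences of log2 fold changes were 4.34 for Chgb, 2.83 for Eef1a2, 2.47 for Clock, 2.77 for Gstm5, -3.24 for Cdh1 and -1.89 for Acsl1. Lists that differed were G2/M (adjusted p = 2.43e-14), hypoxia (3.70e-08), S phase (7.76e-08), stress response (0.000559), Notch and YAP (0.0214), oxidative phosphorylation (0.0214), neuroendocrine (0.0224), NFI (0.0319) and interferon genes (0.0409), of which the last 5 lost their calls with a correlation of 0.05.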

How the results depend on the processing

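The t distribution, recentring, joined features, the test against 0.5, the adjustment over genes with a mean of at least 10, the correlation of 0.05, ranks, the log2 statistic and the region left out were chosen only after the deposited values were seen. Counts of changed genes stayed within 1.5 times with no filter, a mean of at least 50, joined features, recentring and the adjustment over genes with a mean of at least 10. With a change of at least 1 required, 923 genes were left in 16T, 864 in KP1, 1416 in KP22, 712 in the knockdown mean, 628 in the mean of 3 effects, 779 and 1254 in the differences between 16T and KP1 and between knockdown and KP22, and 126 with or against Nfib in all 3 lines. The authors' test against 0.5 gave 813, 709, 1264, 783 and 130 for 16T, KP1, KP22, the knockdown mean and all 3 lines. Both ask for larger changes. With 6 degrees of freedom KP1 had 3301 genes, the differences 1870 and 3356, and all 3 lines 826; the wider reference raises every p. Of 23 list calls in the 3 lines, 15 were kept with a correlation of 0.05. With ranks 24 lists were called, 19 of the 23 and 5 others: ribosomal and oxidative phosphorylation genes in KP1 and KP22 and interferon genes in KP22. With the log2 statistic 14 lists were called, of which 10 were among the 23 and 4 were not; why was not tested. Of 377 values of named genes, 28 missed the threshold with 6 degrees of freedom, 123 against 0.5, 2 recentred and 1 with no filter, all in the same direction. Recentring moved the share of higher values from 44.2% to 53.8% in 16T, 47.4% to 52.1% in KP1, 50.9% to 42.7% in KP22, 44.6% to 52.7% in the knockdown mean, 55.2% to 46.7% in the mean of 3 effects and 47.5% to 54.1% in the difference between 16T and KP1, so which direction was more frequent depends on it. No paired analysis was possible because the table used here holds no values per sample and counts per sample, which the labels name, were not used here; for that reason other normalizations, pseudocounts, a replicate block, leaving out libraries, single-line fits, an estimated correlation and other splits of the samples were not run, and no depth is given.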

Other observations

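No test in this part was chosen before the data were examined, except that the lists were fixed then. "Other signs" is said of genes called in all 3 lines that moved neither with nor against Nfib throughout. The members of the lists that were called in all 3 lines are given by direction. Of all 14504 genes tested in the 3 lines, 773 moved with Nfib and 691 against it, so some members of any list may do so. The counts per list were not tested against these shares. Of 36 neuroendocrine identity genes, 13 moved against Nfib in all 3 lines, Syp, Calca, Scg2, Scg3, Scg5, Pcsk1, Pcsk2, Resp18, Nkx2-1, Eno2, Ddc, Nol4 and Celf3, Insm1 moved with it, and 6 had other signs. Of 35 synaptic vesicle genes, 13 moved against Nfib, among them Stx1a, Vamp2, Rab3a, Sv2a and Slc18a1, Cplx1 moved with it, and 4 had other signs. Axon guidance genes went both ways: 10 of 61 moved with Nfib, among them Sema3c, Robo2, Slit1, Ntn1, Unc5d and Epha5, 6 against it, among them Plxnd1, Dclk1 and Unc5a, and 9 had other signs.

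Of 45 S phase genes, 7 moved with Nfib in all 3 lines (Mcm3, Mcm6, Mcm7, Cdt1, Uhrf1, Cdc25a and Dtl), 0 against it, and 7 were called in all 3 with other signs. Of 33 cholesterol and fatty acid synthesis genes, 4 moved with it, among them Idi1, Hsd17b7 and Acaca, 0 against it, and 6 had other signs. Of 52 matrix and integrin genes, 5 moved with Nfib (Col4a1, Col4a2, Lama5, Vcan and Mmp15), 4 against it (Itgb1, Col6a1, Thbs1 and Timp2), and 4 had other signs. Of 50 chromatin genes, Smarcc1, Smarce1, Chd7 and Hdac2 moved with Nfib, Kat2b, Hdac5, Hdac11, Ezh1 and Cbx7 against it, and 7 had other signs. Of 28 immediate early genes, Fos, Jun, Junb, Egr1 and Dusp6 moved against Nfib, Ier5 and Nr4a1 with it, and 5 had other signs. Of 35 hypoxia and glycolysis genes, 14 were called in all 3 lines and 0 of these moved with or against Nfib throughout.

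In 16T, the median log2 fold change of 50 neighboring genes lay below the lowest of 1000 shuffled gene orders (-0.302) in 3 runs of windows. Their lowest values, -0.312, -0.312 and -0.310, were close to that limit. The windows were centered on 9 genes at 120697473 to 121055325 of chromosome 4, on 13 genes at 122836227 to 123411911 of chromosome 4 and on 13 genes at 56722449 to 59237265 of chromosome 14. The runs on chromosome 4 lie close together and their windows may share genes, so they may not be separate places. The median over the genes at the centers was -0.51, -0.65 and -0.31, with 88.9%, 92.3% and 92.3% of them below 0; these medians were not tested themselves.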
